A study of Mus musculus with 4 samples.

How the data were processed

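The series holds 4 single-cell libraries of CD45+ cells from healthy mouse liver, 2 from the portal vein zone and 2 from the central vein zone, grouped by the zone given in the labels and numbered by the titles. Per the labels' protocols, droplets and libraries were made with the 10x Chromium Next GEM 3′ v3.1 chemistry, which counts molecules by unique molecular identifiers (UMIs) near the 3′ end of transcripts. The authors deposited raw UMI counts per gene and barcode, 1 matrix per library, with 32285 genes each and at least 500 UMIs per barcode. Per the submitters' processing notes, Cell Ranger 4.0.0 and the build mm10 were used. The annotation and the settings for calling cells are not given in the sources used here. Gene symbols were matched for 32158 identifiers, 52 of which share a symbol and were kept apart. Gene positions come from GENCODE vM21 on GRCm38.

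Cells were kept with at least 200 detected genes and at most 10% mitochondrial UMIs, limits fixed before the data were examined. A further step was chosen after the barcodes were seen and before any comparison was run. Of 1939 distinct barcodes, 282 were present in more than 1 library, and each such barcode was kept only in the library that held at least 70% of its UMIs. This removed 221 and 138 barcodes from PV replicates 1 and 2, and 184 and 173 from CV replicates 1 and 2. The filter fixed beforehand, without this step, was also run for each comparison of the report and for the added gene and list tests. The step took the cells of PV replicate 1 from 547 to 331 and its macrophages from 108 to 20. Doublets were called per library with scrublet in scanpy 1.11.5 at a rate of 3%, which marked 2, 7, 3 and 1 cells, and were left out.

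Cells were scaled to 10000 UMIs, log-transformed and clustered on 2000 variable genes, 20 principal components and 15 neighbours with the Leiden method at resolution 1. A cluster was given the name with the highest mean standardised expression over the 23 marker lists fixed beforehand, if at least 3 of that list's markers were each detected in at least 10% of its cells and no other list had more markers among its 10 leading genes by fold, with 20 CPM added on both sides. A cluster far shallower than its libraries also needed a marker among these genes. At resolution 2, a neutrophil-like cluster of 13 cells led by Cxcl2 had 0 markers among its leading genes. Clusters led by Csf2, Ifng and Cd40lg and by immunoglobulin genes stayed unnamed. A shallow cluster of 35 cells (median 1473 UMIs) counted as Kupffer cell-like, with Marco its only marker among the leading genes. Macrophages are the Kupffer cell-like and other macrophage-like clusters. Differences in classes between settings may come from rebuilt names.

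Raw counts were summed per library and class, since cells are not replicates. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05, on 2 residual degrees of freedom. Only classes with at least 20 cells in every library were tested, which left macrophages and T cells. DESeq2 1.42.0 was the other tool. Class shares were tested in edgeR on cell numbers with the library total as offset. Of 21 gene lists fixed beforehand, 17 were tested in macrophages and 4 zonation lists in the all-cell sums, with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry of limma 3.58.1, for lists with at least 5 tested genes. For shares of cells with a Marco or Il10 UMI, each macrophage was thinned to 3087 UMIs, the 25th percentile, and shallower cells were left out. Marco-positive and Marco-negative cells were summed per library, without Marco itself, and tested in edgeR with the library as a block. Intervals are 95% Wilson intervals, and a count of 0 allows up to 3 counts; both cover counting error only.

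Genes were named by a rule fixed before the data were examined: a fixed set of macrophage genes, the genes past the test with the largest changes and all libraries of a zone on 1 side, then those with the smallest p, given as not past the test. Gene models without a proper name were not named. Within lists, the members with the smallest p were named. Genes outside the rule, namely those of the added tests, the markers Spp1, Ace, Lyz2 and Ceacam1 of single clusters or libraries, and the single pericentral genes, were chosen after their values were seen.

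The edgeR gene test was tested on simulated data with 200 changed genes, for the zones in all cells, macrophages and T cells and for Marco states. For 2-, 4- and 8-fold changes, it recovered 5.97%, 73.4% and 85.7% in all-cell sums over 10217 genes (22 false calls), and 1.59%, 65.6% and 91.5% in macrophages over 5497 genes (8 false calls). It recovered 38.5%, 90.5% and 96.6% in T cells over 6879 genes (11 false calls), and 76.7%, 96.6% and 100% for the Marco states over 995 genes (5 false calls). The false calls were over 5% of the calls in all cells, macrophages and T cells. A moved gene list in macrophages had a camera adjusted p of 4.5e-12, and 0 of the other lists were called. No such check is given for class shares, for fry, for camera with an estimated correlation or for the difference between macrophages and T cells.

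Alternatives fixed beforehand were DESeq2's size factors in edgeR, DESeq2, no filter on low counts, the title number as a block, leaving out each library, at least 500 genes with at most 5% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2, thinned cells, Kupffer cell-like clusters alone, other list tests, and for Marco no thinning, the 50th percentile, at least 2 UMIs and no library term. Alternatives chosen after seeing the data were shared barcodes kept, at least 1000 UMIs per cell, classes with at least 10 cells, the lists in other sums and in Kupffer cell-like clusters, and a test of the difference of the zone effect between macrophages and T cells. The added tests with shared barcodes kept, the zonation ratio without Ctsc, the pro-inflammatory list without Ccl3 in T cells, Serpina3g and Plac8 UMIs by the class at another resolution, and the counts of cells that carry a gene's UMIs or both a Marco and an Il10 UMI were also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.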

Results

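Single-cell RNA sequencing was done on CD45+ leukocytes from healthy livers of C57BL/6 mice that carry PA-GFP, a green fluorescent protein switched on by light, so that cells of an illuminated zone can be told from the rest. Cells came from the zone around the portal vein (PV), where blood from the gut enters the liver, or from the zone around the central vein (CV), where blood leaves it, with 2 libraries per zone. The deposited matrices held 622 and 755 barcodes for PV replicates 1 and 2, and 624 and 588 for CV replicates 1 and 2. Their total UMI counts were 3063778, 4373488, 2741760 and 2916638. After filtering, 331, 505, 369 and 375 cells remained, with medians of 6205, 6221, 5372 and 5615 UMIs per cell. Nothing in the labels says that the libraries came from separate mice, so p-values measure the spread between these libraries, which may be technical. As a check for duplicate libraries, the all-cell sums of a zone's libraries were compared, and differed with a chi-square per degree of freedom of 18.6 over 10851 genes in PV and 11.8 over 10216 genes in CV, values that the makeup of the cells enters.

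The makeup of the immune cells was compared between the zones. T cells were the most frequent class, at 43.0% ± 18.6 of cells in PV and 33.9% ± 0.00566 in CV (SD, n = 2 per zone). Natural killer (NK) cells made up 3.79% ± 1.08 in PV and 12.1% ± 1.76 in CV, and were lower in both PV libraries than in both CV libraries. Type 1 conventional dendritic cells (cDC1), which present antigen to CD8 T cells, made up 8.06% ± 3.56 and 3.77% ± 0.803, and type 2 dendritic cells (cDC2) 4.79% ± 0.0580 and 1.88% ± 1.12. Macrophages made up 17.0% ± 15.5 in PV and 16.8% ± 1.90 in CV. The PV libraries lay far apart, at 20 of 331 cells (6.04%, 95% Wilson interval 3.95 to 9.15) and 141 of 505 (27.9%, 24.2 to 32.0). B cells, neutrophils, plasmacytoid dendritic cells and sinusoidal endothelial cells averaged 7.42%, 4.61%, 1.74% and 1.44% in PV, and 12.1%, 7.01%, 1.74% and 0.534% in CV. Cells of clusters left unnamed averaged 8.12% in PV and 10.2% in CV.

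None of the 9 classes differed between the zones in edgeR's quasi-likelihood test. The NK share had a log2 ratio of -1.65 ± 0.89 (SE) and an edgeR adjusted p of 0.548, and no class had an unadjusted p below 0.05. With 2 libraries per zone, an exact two-sided permutation test cannot give a p below 0.333. With barcodes shared between libraries kept, which was the cell filter fixed beforehand, the cDC1 log2 ratio was -0.32 in place of 1.08, and the NK log2 ratio was -0.55. The cDC1 class then held 45 and 30 cells in PV and 43 and 45 in CV, in place of 35, 28, 16 and 12. Its median depth fell from 22855 and 21486.5 UMIs to 16518 and 16880 in PV. In CV it fell from 20952.5 and 21719.5 to 1756 and 1730. The median depth of NK cells fell from 3997.5 and 5339 UMIs to 613 and 687 in PV, and from 4786.5 and 5039.5 to 4306 and 4315 in CV. A cluster led by Ccl22 and Cxcl9, with the cDC2 genes Cd209a and Mgl2, stayed unnamed there and no cluster was cDC2-like. Leaving out a library turned the log2 ratio of macrophages from 0.03 to -1.47 (without PV replicate 2) or -0.0893 (without CV replicate 2), of T cells from 0.34 to -0.18 (without PV replicate 1), of neutrophils from -0.63 to 0.19 (without CV replicate 1), of plasmacytoid dendritic cells from 0.0752 to -2.40 (without PV replicate 2) or -0.23 (without CV replicate 1), and of endothelial cells from 1.46 to -0.76 (without PV replicate 2).

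**Figure D1:**
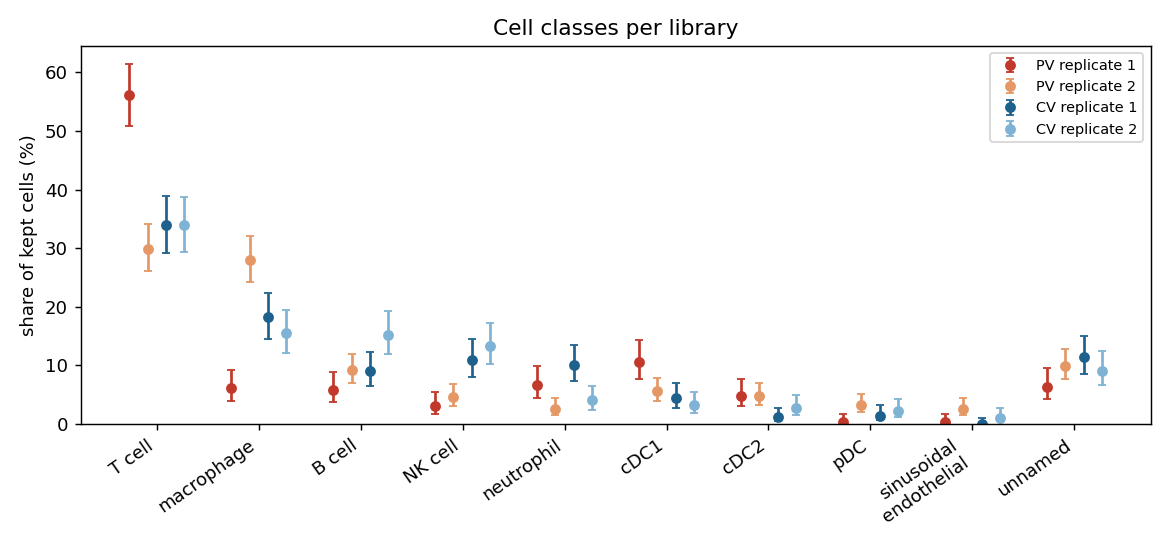
Share of kept cells in percent (vertical axis) for each cell class (horizontal axis), with 1 point per library and 95% Wilson intervals that cover counting error only. NK cells made up 3.02% and 4.55% of the PV libraries and 10.8% and 13.3% of the CV libraries, and the macrophage shares of the PV libraries were 6.04% and 27.9%.

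Macrophages, the cells named in the series title, were compared between the zones by summing their UMIs per library. Gdf15, which encodes a stress-induced cytokine of the TGF-beta superfamily, was higher in PV macrophages by a log2 fold change of 3.61 ± 0.38 (SE, n = 2 per zone, edgeR adjusted p = 0.0404). It lies on chromosome 8 at 70629393 to 70632456 of GRCm38. It stood at 317 and 288 CPM (UMIs scaled to a common library total) in PV and at 19.0 and 33.1 CPM in CV, from 49, 318, 10 and 15 UMIs. These UMIs lay in 3 of 20 and 14 of 141 macrophages in PV and in 5 of 67 and 4 of 58 in CV, and a single cell held 46 of the 49 in PV replicate 1 and 135 of the 318 in PV replicate 2. Gdf15 was also a leading gene of a cluster of other macrophage-like cells, which held 7 of 20 and 11 of 141 macrophages in PV and 7 of 67 and 11 of 58 in CV.

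Further genes leaned the same way in both libraries of a zone and did not pass the test. Cd63, a lysosomal membrane protein, was at 510 and 151 CPM in PV and 13.3 and 11.03 CPM in CV, and Ms4a7 at 543 and 254 against 118 and 59.5 CPM. Both led another cluster of macrophages outside the Kupffer cell-like ones. Mgl2, a lectin receptor that also led the cDC2 cluster, had 22 and 48 UMIs in PV and 0 in both CV libraries, at least 18.2-fold higher against a floor of 3 counts over the CV group. Pmepa1 had 60 UMIs in PV and 2 in CV, a ratio of 23.4 with a counting interval of 6.20 to 197. Plac8 was at 136 and 271 CPM in PV and 454 and 697 CPM in CV. Irak3, an inhibitor of Toll-like receptor signalling, was at 6.46 and 20.9 against 70.3 and 50.7 CPM, from 1, 23, 37 and 23 UMIs. Ceacam1 (log2 fold change -2.57 ± 0.60, from 1, 7, 15 and 23 UMIs), Spn (-1.90 ± 0.64, from 2, 10, 11 and 25 UMIs) and the noncoding RNA AY036118 (-1.05 ± 0.33) were also lower in both PV libraries. These genes had edgeR adjusted p-values of 0.928 or more.

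The genes fixed beforehand did not pass the test either. Marco, a scavenger receptor that binds bacteria, had a log2 fold change of -0.83 ± 0.61 (SE), at 342 and 440 CPM in PV and 1134 and 291 CPM in CV. Il10, an anti-inflammatory cytokine, had -0.73 ± 1.39, at 64.6 and 52.6 CPM in PV and 179 and 6.62 CPM in CV. Both are genes for which the study is known, so they are not independent of these samples. Of the Kupffer cell genes, Clec4f had -0.60 ± 0.72, Timd4 -0.68 ± 0.74, Vsig4 -0.73 ± 0.82, Cd163 -0.32 ± 1.24 and Cd5l -0.92 ± 0.87. Adgre1, C1qa and Mrc1 had -0.63 ± 0.45, -0.25 ± 0.37 and -0.31 ± 0.41, while Cx3cr1, Ccr2 and Cd74 had 2.07 ± 1.27, 1.40 ± 1.43 and 0.37 ± 0.53. Lyve1 had too few counts to be tested.

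In all, 1 of 5923 genes passed edgeR's test between macrophages of the zones, and 94 had an unadjusted p under 0.05. DESeq2 called 3 genes. PV replicate 1 held only 4 Kupffer cell-like cells (1.21%, 95% Wilson interval 0.471 to 3.07), against 120, 56 and 40 in PV replicate 2 and CV replicates 1 and 2. That number follows from a filter chosen after the barcodes were seen, and with shared barcodes kept it was 69 of 547 (12.6%), Gdf15 had a log2 fold change of 2.36 with an edgeR adjusted p of 0.0185, and 2 genes passed. The Gdf15 call was lost with stricter cell limits (edgeR adjusted p = 0.279), with doublets kept (0.0554), with at least 1000 UMIs per cell (0.0668), at clustering resolutions 0.5 and 2 (0.234 and 0.0885), in thinned cells (0.488) and within Kupffer cell-like clusters alone (log2 fold change 1.13, adjusted p = 0.9997). The number of genes past the test was 20 without PV replicate 1, 432 without PV replicate 2, 7 without CV replicate 1 and 8 without CV replicate 2.

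**Figure D2:**
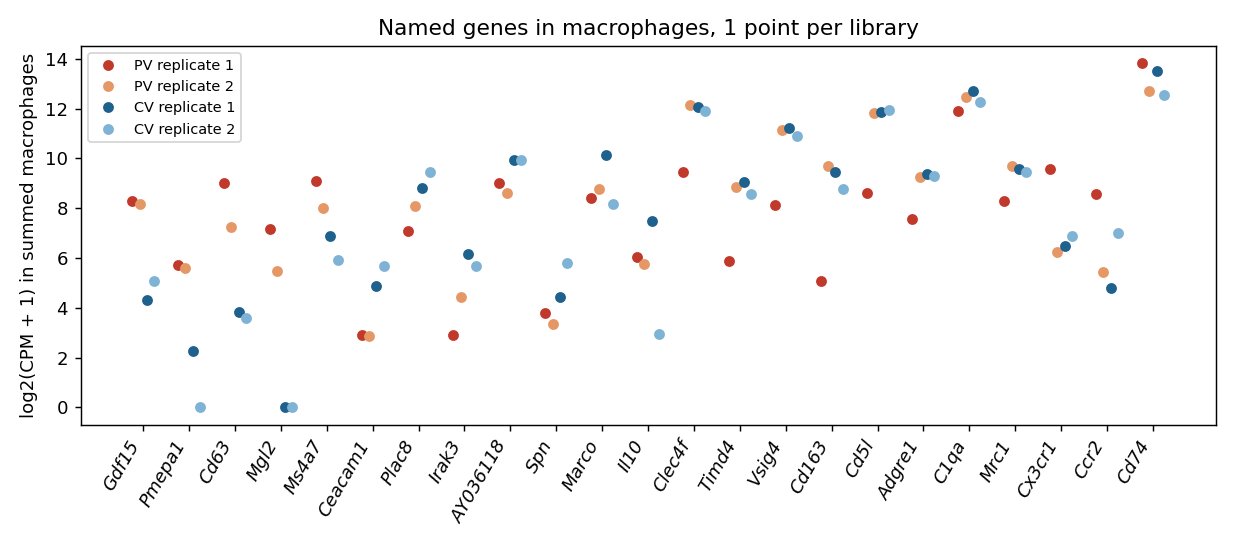
Expression of the named genes in summed macrophages as log2(CPM + 1) (vertical axis), with 1 point per library. Gdf15 was at 317 and 288 CPM in PV and 19.0 and 33.1 CPM in CV, and the Kupffer cell genes Clec4f to Cd5l were lowest in PV replicate 1, which held 4 Kupffer cell-like cells.

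Gene lists fixed beforehand were tested in the same macrophage sums with camera at a preset correlation. Immediate early and dissociation response genes were higher in PV, with 21 of 23 members above 0 (median log2 fold change 0.47, camera adjusted p = 2.8e-06, and adjusted p = 0.717 with an estimated correlation), among them Dnajb1 (1.19 ± 0.52), Btg2 (0.65 ± 0.33) and the transcription factor Atf3 (0.83 ± 0.44). Pro-inflammatory cytokines and chemokines were higher in PV, with 11 of 18 members above 0 (median 0.46, camera adjusted p = 0.021, and adjusted p = 0.717 with an estimated correlation). Of these, Il1a had 1.17 ± 0.43, Ccl3 went the other way at -0.998 ± 0.45, and Ptgs2 was at 25.9 and 21.8 CPM in PV and 0 in both CV libraries. In PV replicate 1 macrophages, the 51.7 CPM of Pmepa1 came from 8 UMIs, so Ptgs2 rested on fewer than 8 there. Kupffer cell identity genes were lower in PV in 18 of 20 members (median -0.80, camera adjusted p = 0.00024, and adjusted p = 0.717 with an estimated correlation), among them C6 (-1.04 ± 0.74) and Id1 (-0.47 ± 0.37). Complement genes were lower in 14 of 19 members (median -0.26, camera adjusted p = 0.021, and adjusted p = 0.717 with an estimated correlation). Itgax, a chain of complement receptor 4 and the member with the smallest p, went the other way at 2.06 ± 0.69, while C4b had -1.001 ± 0.44 and Cd55 -1.49 ± 0.65. Monocyte-derived macrophage genes were lower in 11 of 15 members (median -0.35, camera adjusted p = 0.021, and adjusted p = 0.717 with an estimated correlation), with Plac8 at -1.39 ± 0.37 and Lgals3, a member that went the other way, at 2.41 ± 0.88. Monocyte markers stood at 1092 and 874 CPM in PV macrophages and at 1160 and 1793 CPM in CV macrophages. That marker list holds Plac8 and Spn and shares further genes with the monocyte-derived list, so its sum is not independent of them. Plac8 alone was at 136 and 271 CPM in PV and 454 and 697 CPM in CV. At resolutions 0.5 and 2 and with at least 1000 UMIs per cell, a cluster led by Ace, with Lyz2 and Ceacam1, lay outside the macrophages, with 2, 3, 1 and 9 cells of PV replicates 1 and 2 and CV replicates 1 and 2. With stricter cell limits it was monocyte-like, with 2, 2, 1 and 8 cells. Plac8 had -1.06, -1.07 and -1.04 at resolution 2, with at least 1000 UMIs and with stricter limits. It had 0.38 at resolution 0.5, where 16, 24, 4 and 10 cDC2 cells also counted as macrophages and held 225, 471, 88 and 96 Plac8 UMIs, against 3, 290, 209 and 119 in the others.

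These were 5 of the 17 lists tested. With an estimated correlation none of the 5 calls held, and fry called none (adjusted p = 0.922 for each). No member of any list passed edgeR's test over all genes. Adjusted over the list alone, 2 members of the Kupffer subset list with endothelial genes, 1 of the lysosome list and 1 of the capsular and central vein macrophage list passed, all higher in PV. The camera adjusted p was 0.155 for the Kupffer subset with endothelial genes, 0.323 for MHC class II presentation and for lysosome genes, 0.453 for lipid handling, 0.468 for tissue residency and adhesion, 0.766 for scavenger receptors and 0.951 for interleukin 10 and anti-inflammatory genes. It was 0.697 for the type I interferon response, iron and heme handling, efferocytosis, capsular and central vein macrophage genes and cytotoxicity, the last with a median above 0 and a test direction below 0. Sinusoidal endothelial markers stood at 381 and 380 CPM in PV macrophages and at 199 and 179 CPM in CV macrophages. Without PV replicate 1, Kupffer cell identity genes had a median of 0.10, and within Kupffer cell-like clusters 0.03. The pro-inflammatory list had a median of -0.11 without CV replicate 2, and the monocyte-derived list 0.30 without PV replicate 2. With shared barcodes kept 4 of 17 lists passed, and the pro-inflammatory and monocyte-derived lists did not (camera adjusted p = 0.382 and 0.0784).

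Macrophages with a Marco UMI were counted after each cell was thinned to 3087 UMIs, which left out 4, 31, 22 and 15 shallower cells of PV replicates 1 and 2 and CV replicates 1 and 2. Marco was detected in 3 of 16 (18.8%, 95% Wilson interval 6.59 to 43.0) and 33 of 110 (30.0%, 22.2 to 39.1) PV macrophages. In CV it was detected in 26 of 45 (57.8%, 43.3 to 71.0) and 12 of 43 (27.9%, 16.7 to 42.7). The mean was 24.4% ± 7.96 in PV and 42.8% ± 21.1 in CV (SD, n = 2 per zone), a difference of -18.5 percentage points that rested mainly on CV replicate 1 and fell to -3.53 points without it. With shared barcodes kept it was -13.7 points, from 13.1% and 18.7% in PV and 40.6% and 18.6% in CV, and for Il10 -0.94 points. Without thinning 4 of 20 cells and 41.1% had Marco in PV and 71.6% and 31.0% had it in CV. Il10 was detected in 5.85% ± 0.562 of PV and 7.83% ± 7.78 of CV macrophages, from 1, 6, 6 and 1 cells, and without thinning in 1 of 20 cells, 5.67%, 17.9% and 5.17%.

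Over the 4 libraries, 74 of 214 thinned macrophages had a Marco UMI, 14 had an Il10 UMI and 7 had both. All 74 and all 14 lay in Kupffer cell-like clusters, and Marco is itself a marker of that class. T cells, which should lack Marco, had a Marco UMI in 0 of 168, 1 of 141, 2 of 112 and 0 of 123 cells. They had an Il10 UMI in none, although some T cells can make it. Here 0 of 168 cells allows up to 1.79% with a UMI at this depth, which sets no limit on the share of T cells that make Il10. Their median depth before thinning was 6552, 6422, 5924 and 6234 UMIs, against 7540, 7851, 10017 and 9075 in the macrophages. Within Kupffer cell-like clusters the Marco shares were 3 of 3 cells, 35.5%, 68.4% and 42.9%, so that the difference turned to 12.1 points on the 3 cells of PV replicate 1. The smallest p of an exact permutation test of 2 against 2 libraries is 0.333, so neither share could pass a threshold of 0.05.

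**Figure D3:**
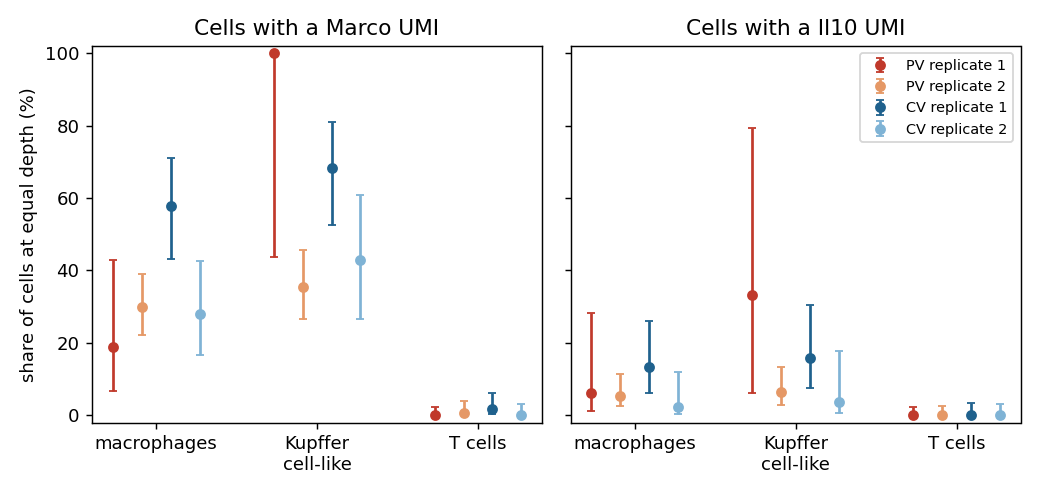
Share of cells with a Marco UMI (left) or an Il10 UMI (right) in percent after thinning to 3087 UMIs, with 1 point per library and 95% Wilson intervals that cover counting error only. In macrophages the Marco share was 18.8% and 30.0% in PV and 57.8% and 27.9% in CV, and T cells had Marco in at most 1.79% of cells.

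Marco-positive and Marco-negative macrophages were compared within each library. Some genes of MHC class II antigen presentation were lower in Marco-positive cells, while the list as a whole was not tested between Marco states. These were H2-Eb1 by a log2 fold change of -1.62 ± 0.23 (SE, edgeR adjusted p = 0.0065), H2-Ab1 by -1.61 ± 0.23 (0.0065), H2-Aa by -1.17 ± 0.22 (0.0302) and the invariant chain Cd74 by -1.15 ± 0.18 (0.0103). The stress-responsive transcription factor Atf3 was lower by -1.49 ± 0.25 (edgeR adjusted p = 0.0134). The chemokine receptor Cx3cr1 had 0 UMIs in Marco-positive and 105 in Marco-negative cells, at least 18.5-fold lower against a floor of 3 counts over the 4 sums (edgeR adjusted p = 0.0065). Each of these 6 genes was lower in the positive sum of all 4 libraries. Ckb (1.20 ± 0.30), Sowahc (1.05 ± 0.28) and mt-Co3 (0.59 ± 0.19) were higher in all 4 and did not pass the test.

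These were the 6 genes past edgeR's test among 1067, all lower in Marco-positive cells, with 131 genes at an unadjusted p under 0.05. DESeq2 called 24. The positive sums held 3, 33, 26 and 12 cells, all Kupffer cell-like, and a detected UMI marks a range of expression, not a cell type. The negative sums held 13, 77, 19 and 31 cells, of which 13, 17, 7 and 15 were other macrophage-like. Within Kupffer cell-like clusters, where PV replicate 1 gave 0 Marco-negative cells, none of 1106 genes passed (66 at an unadjusted p under 0.05), with H2-Ab1 at -0.73 ± 0.17, H2-Aa at -0.62 ± 0.15, Cd74 at -0.39 ± 0.14, Atf3 at -0.46 ± 0.33 and H2-Eb1 at -0.24 ± 0.18. No gene passed without PV replicate 2 or without CV replicate 2, 25 passed without PV replicate 1, and 55 with shared barcodes kept.

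All kept cells of a library were also summed, a comparison that mixes makeup and expression. The dendritic cell lectins Clec10a (log2 fold change 2.02 ± 0.24 SE) and Cd209a (1.85 ± 0.27) and the lipid receptor Trem2 (1.70 ± 0.28) were higher in both PV libraries. The NK cell receptor Ncr1 (-1.93 ± 0.29), Cd7 (-1.33 ± 0.21) and the signalling inhibitor Spry2 (-1.19 ± 0.21) were lower in both. Clec10a was at 56.1 and 47.8 CPM in PV and 14.3 and 11.7 CPM in CV, and Ncr1 at 16.0 and 26.9 against 70.3 and 95.4 CPM. Clec10a and Cd209a are markers of cDC2 and Ncr1 of NK cells, whose shares leaned the same way. Cd7, in the marker list of cDC2, was a leading gene of the NK cell-like cluster.

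None of 10509 genes passed edgeR's test in the all-cell sums, and 215 had an unadjusted p under 0.05. DESeq2 called 9. The count was 32 without PV replicate 1 and 263 without PV replicate 2, 142 with no filter on low counts, and 0 of 10657 genes with shared barcodes kept.

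T cells were the only other class with at least 20 cells in every library. Ccl3, a chemokine that draws in leukocytes, was lower in PV T cells by a log2 fold change of -3.78 ± 0.49 (SE, n = 2 per zone, edgeR adjusted p = 0.0048). It lies on chromosome 11 at 83647844 to 83649355 of GRCm38, and had 2 and 4 UMIs in PV and 34 and 29 in CV. These lay in 2 of 186, 3 of 151, 4 of 125 and 4 of 127 T cells, and a single cell held 31 of the 34 in CV replicate 1 and 23 of the 29 in CV replicate 2. The T cell class pools 3 clusters in differing mixes. The cluster led by Cxcr6 and Inpp4b made up 66.1% and 34.4% of PV and 36.8% and 28.3% of CV T cells, that led by Ctla2a and Trac 29.0% and 47.0% against 56.8% and 50.4%, and that led by Dapl1 and Cd8b1, with no Ccl3 UMI, the rest. Xcl1, a chemokine for cDC1, was at 219 and 319 CPM in PV and 566 and 796 CPM in CV, and Ybx3 at 23.5 and 34.4 against 49.6 and 69.6 CPM. Ifngr1, a chain of the interferon gamma receptor, was at 523 and 454 CPM in PV and 385 and 262 CPM in CV, and Mfsd6 at 28.7 and 34.4 against 11.03 and 10.4 CPM. Fam199x had 32 UMIs in PV and 3 in CV, a ratio of 8.03 with a counting interval of 2.51 to 41.0. These 5 genes did not pass the test (edgeR adjusted p = 0.999 for each). NK cell markers, whose cells also make Ccl3 and Xcl1, stood at 394 and 336 CPM in PV T cells and at 380 and 335 CPM in CV T cells.

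In all, 1 of 7187 genes passed edgeR's test in T cells, 243 had an unadjusted p under 0.05, and DESeq2 called 2. With doublets kept Ccl3 had a log2 fold change of -4.28 and an edgeR adjusted p of 0.300. The T cell class there held 203, 196, 165 and 158 cells in place of 186, 151, 125 and 127, and the cluster led by Csf2, Ifng and Cd40lg, unnamed without the doublets, was then T cell-like. With shared barcodes kept Ccl3 was not among the tested genes and no gene passed. The count was 11 without PV replicate 1, 16 without PV replicate 2, 55 without CV replicate 1 and 10 without CV replicate 2.

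Genes known to be zoned in hepatocytes and endothelial cells were compared with the zone labels in the all-cell sums. Pericentral hepatocyte genes had a median log2 fold change of -0.37 in PV over CV, periportal endothelial genes 0.91 and central endothelial genes 0.37. Sinusoidal endothelial cells numbered 1 and 13 in PV and 0 and 4 in CV, so cell makeup enters both endothelial medians. The periportal endothelial list also holds Msr1 and Il1a, which are members of lists tested in macrophages. Zonation of endothelial cells was not separated from makeup. The log2 ratio of pericentral to periportal hepatocyte UMIs was -1.02 ± 0.47 in PV and -1.30 ± 0.19 in CV (SD, n = 2 per zone), a difference smaller than the spread between the PV libraries, and without Ctsc, left out after the values were seen, 1.03 ± 0.37 in PV and 1.63 ± 0.0780 in CV. The PV minus CV difference with Ctsc was 0.28, and 0.21 with shared barcodes kept. Ctsc, which macrophages also express, made up 63.7% to 87.6% of the periportal UMIs. Most of the remaining periportal UMIs were of Ass1 (118 and 182 in PV, 68 and 85 in CV) and Asl (50 and 76 in PV, 48 and 45 in CV). Whether hepatocytes were their source was not tested, so the ratio without Ctsc does not measure hepatocyte RNA alone. Of the pericentral UMIs, 23.1% to 65.0% lay in macrophages, and 77.2% to 88.9% came from Glul, Oat, Cyp27a1 and Mgst1, which cells other than hepatocytes also express, while Cyp1a2 had 0 and 4 UMIs in PV and 3 and 2 in CV. Cyp2e1, an enzyme of pericentral hepatocytes, was at 1.49 and 4.83 CPM in PV and 5.05 and 18.5 CPM in CV, from 4, 19, 12 and 49 UMIs, and did not pass the test (log2 fold change -1.83 ± 0.80, edgeR adjusted p = 0.9997). None of the 3 tested lists passed camera (adjusted p = 0.302, 0.140 and 0.140), the estimated correlation (0.491 for each) or fry (0.742 for each). Adjusted over the list alone, 1 periportal endothelial gene passed, higher in PV. Fewer than 5 periportal hepatocyte genes had enough counts to be tested. Without PV replicate 1, 3 of 4 lists passed, and the pericentral list had a median of 0.34, and 0 of 3 passed with shared barcodes kept.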

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

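The tests of chance barcodes, of the zone as the source of the Kupffer cell-like share, of other splits of the sums and of other macrophage clusters, the origin of the Kupffer cell-like cells and the test of the difference between macrophages and T cells, also with shared barcodes kept, were chosen only after the results were seen.

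Of 1939 distinct barcodes, 282 occurred in more than 1 library and 152 of them in all 4; the copies outside an owner library are data that the comparisons did not use, except with shared barcodes kept, and the series has no control samples. Against different cells that drew the same barcode by chance, profiles with the same barcode correlated more than profiles with other barcodes by at least 0.182 in each of the 6 library pairs. Reads of 1 library assigned to another remain a candidate explanation: a smaller copy had 99.5% of its UMIs in genes detected in its owner and 83.8% in a matched other cell, a median difference of 15.59 percentage points, higher in 467 of 467 copies. For the 66 barcodes without an owner, with a median of 840 UMIs per copy, no separate test was run. No biological explanation was tested.

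PV replicate 1 held 4 Kupffer cell-like cells among 331 (1.21%), against 10.7% to 23.8% in the other libraries. The zone alone is argued against by PV replicate 2, whose share of 23.762% lay above both CV libraries, and loss to the limits on genes and mitochondrial UMIs by only 6 failing barcodes with at least 2 of 4 Kupffer cell markers. By the share alone, removal of shared barcodes could not be told apart from a real shortage in that library. With them kept the share was 12.614%, between the bounds set for either outcome and below the 15.963% to 23.631% of the others. Of those 69 cells, 45 had an owner in another library (median 720 UMIs), 20 had no owner (857 UMIs) and 4 were its own (4446.5 UMIs). In PV replicate 2 and CV replicates 1 and 2, 121, 57 and 39 such cells were their own, and 14, 18 and 20 had no owner. If copies with an owner are reads of other libraries, PV replicate 1 stayed lowest even with its cells without an owner counted. On that condition, these counts argue against removal of shared barcodes as the only source of the shortage. A difference in the tissue sampled for that library remains open and untested.

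The 6 genes lower in Marco-positive macrophages, among them Cx3cr1, Cd74 and H2-Ab1, were weighed against chance and against cell makeup. The count over all splits could not decide on chance: 3 of 32 splits of the 8 sums, the real one included, gave as many genes, and 3 further splits could not be fitted. The others were 2 with 26 genes, several times the real count, that parted the sums of only 2 of the 4 libraries, PV replicate 1 and CV replicate 2. With the library as a block, both compared the Marco-positive with the Marco-negative sums of these libraries. They thus repeat part of the real comparison and are no measure of chance. Of the 8 splits that parted the sums of all 4 libraries, the real one gave 6 genes and the highest other 0, and 8 splits are too few for a share under 0.05. Cells of other macrophage clusters in the Marco-negative sums remain a candidate explanation: over the 5 genes tested in both, the median log2 fold change was -0.459 within Kupffer cell-like clusters and -1.486 over all macrophages. Of the Marco-negative cells, 13 of 13 and 17 of 77 in the PV libraries lay in these other clusters. In the CV libraries it was 7 of 19 and 15 of 31. No Marco-positive cell did, so Marco state and cluster class coincided in PV replicate 1. Cx3cr1 and Atf3 were leading genes of these other clusters, and Cx3cr1 is among the markers that name them. Within Kupffer cell-like clusters, with 0 Marco-negative cells in PV replicate 1, H2-Ab1 went from -1.61 ± 0.23 to -0.73 ± 0.17 and H2-Aa from -1.17 ± 0.22 to -0.62 ± 0.15 (edgeR adjusted p = 0.064 for each), so a difference within Kupffer cells stays open.

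The zone effect differed between macrophages and T cells for 3 of 8643 genes by an edgeR test of the difference, namely Alb, Ahsg and Ttr, transcripts of proteins secreted by hepatocytes (259 genes at an unadjusted p under 0.05). Their UMIs in T cells lay mostly in PV replicate 2, at 176, 119 and 58 against at most 28, 5 and 2 in any other library. The hepatocyte marker list, which holds Alb and Ttr, had 54 and 403 UMIs in PV T cells and 28 and 22 in CV T cells. RNA of other cells was not separated out of these sums, so the difference does not show a zone effect within T cells. Without PV replicate 1, PV replicate 2, CV replicate 1 and CV replicate 2 the count was 17, 152, 1 and 7, with Alb among the genes each time, and Ahsg and Ttr absent without PV replicate 2 and without CV replicate 1. With shared barcodes kept the count was 0 of 8521 genes (247 at an unadjusted p under 0.05).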

How the results depend on the processing

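Shared barcodes kept, leaving out Ctsc, at least 1000 UMIs, at least 10 cells per class and the list tests in Kupffer cell-like clusters were chosen after seeing the data. Counts of genes between zones moved under most settings, and the cause was not tested beyond the fewer cells or genes that a setting leaves. In macrophages (1 gene) the count was 3 with DESeq2, 28 with no filter on low counts, 2 with shared barcodes kept, 2 in Kupffer cell-like clusters, and 0 with stricter cell limits, doublets kept, at least 1000 UMIs, resolution 0.5, resolution 2 and thinned cells. Leaving out a library gave 7 to 432. In all cells (0 genes) it was 9 with DESeq2, 142 with no filter, and 0 to 263 without a library. In T cells (1 gene) it was 2 with DESeq2, 12 with no filter, 2 with stricter limits, 0 with doublets kept (where the class gained the cluster led by Csf2), 0 with shared barcodes kept, 2 with at least 1000 UMIs (where the class held fewer cells and unnamed clusters more), and 10 to 55 without a library. With classes of at least 10 cells it was 2 over the classes other than macrophages, Ccl3 in T cells and Serpina3g in cDC1.

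The title numbers were not shown to pair the libraries: deviations of same-numbered libraries correlated at 0.0146 in all cells, -0.0368 in macrophages and 0.179 in T cells. With the replicate block the count was 4 in macrophages, 2 in all cells and 22 in T cells, 6 of 17 lists and 1 of 3 zonation lists passed, the macrophage share had a log2 ratio of -0.29 in place of 0.03, the plasmacytoid dendritic cell share -0.18 in place of 0.0752, and Il10 had 0.40 in macrophages.

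Of 17 lists in macrophages, 5 passed camera, 0 with an estimated correlation, 0 with fry, 3 in Kupffer cell-like clusters, 4 with shared barcodes kept, and 2 to 9 without a library. Zonation lists went from 0 to 4 with no filter, and 0 to 3 without a library. The PV minus CV difference of the log2 ratio of pericentral to periportal UMIs was 0.28, -0.60 without Ctsc, which holds most periportal UMIs, and -0.0541 to 0.61 without a library. Genes by Marco state (6) were 34 without thinning, 0 with at least 2 Marco UMIs, 1 with no replicate block (no library term), 24 with DESeq2, 30 with no filter, 0 in Kupffer cell-like clusters, 55 with shared barcodes kept, and 0 to 25 without a library. The Marco share difference was -18.5 points, -13.7 with shared barcodes kept, 12.1 in Kupffer cell-like clusters and -33.4 to -3.53 without a library. That of Il10 was -1.98 points, -8.64 at the 50th percentile, -7.56 with stricter limits, and -7.48 to 3.53 without a library. In Kupffer cell-like clusters it was 10.2, which rested on 1 positive cell of 3 in PV replicate 1. The Il10 share there was 6.45% in PV replicate 2 and 15.8% and 3.57% in CV.

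The following values changed sign, short of the test except the monocyte-derived list; the cause was not tested. Among shares (log2 ratio), cDC1 had -0.32 with shared barcodes kept, where the class in CV gained cells and its median depth fell. T cells had -0.16 with at least 1000 UMIs, where the class held 72, 114, 86 and 99 cells in place of 186, 151, 125 and 127. Without a library T cells ran from -0.18 to 0.73, macrophages from -1.47 to 0.73 and neutrophils from -1.43 to 0.19. Plasmacytoid dendritic cells ran from -2.40 to 0.85 and endothelial cells from -0.76 to 5.63. In macrophages (log2 fold change), Plac8 had 0.38 at resolution 0.5 (where the class gained the cDC2 cells), C1qa 0.0604 in thinned cells, and Marco 0.40, C1qa 0.10 and Cd74 -0.21 in Kupffer cell-like clusters. In T cells Ybx3 had 0.24 with shared barcodes kept. Without a library each, Marco ran from -1.55 to 0.53, Il10 from -1.66 to 3.16, Clec4f from -2.37 to 0.16, Timd4 from -2.82 to 0.0030, Vsig4 from -2.81 to 0.0528 and Cd163 from -3.99 to 0.52. C1qa ran from -0.52 to 0.0224, Mrc1 from -1.06 to 0.14, Cx3cr1 from -0.45 to 3.04, Ccr2 from -0.83 to 2.90 and Cd74 from -0.41 to 0.97. List medians ran from -0.11 to 0.83 for pro-inflammatory genes, -2.40 to 0.10 for Kupffer cell identity (0.0281 in Kupffer cell-like clusters), -1.07 to 0.30 for monocyte-derived genes (camera adjusted p = 0.0208 at 0.30), -0.76 to 0.34 for pericentral hepatocyte genes, -0.47 to 1.28 for periportal and -0.64 to 0.73 for central endothelial genes. Gdf15 and Ccl3 kept their direction wherever they were tested.

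At the cells and UMIs held here, 2-fold changes were recovered for 1.59% of simulated genes in macrophages, of which PV replicate 1 held 20, for 5.97% in all cells and 38.5% in T cells. A lone library of a zone is assumed to vary like the other zone. DESeq2's size factors in edgeR moved no count of genes by over 1.5 times.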

Other observations

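The tests in classes with at least 10 cells per library, with shared barcodes kept, in Kupffer cell-like clusters by list and of lists in other sums were chosen only after the data were seen, while the gene test within Kupffer cell-like clusters was planned.

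Among cDC1, from 35, 28, 16 and 12 cells of PV replicates 1 and 2 and CV replicates 1 and 2, Serpina3g, a protease inhibitor gene, had 91 and 54 UMIs in PV and 0 in both CV libraries (edgeR adjusted p = 0.0063), from 4 of 35 and 4 of 28 PV cells, with 60 of the 91 and 38 of the 54 UMIs in a single cell. The class pools subsets in differing mixes: at resolution 2, 9, 8, 5 and 1 of these cells formed a mature dendritic cell-like cluster, which held 61 of the 91 and 51 of the 54 UMIs. It was the 1 gene of 4480 past edgeR's test (192 at an unadjusted p under 0.05), and DESeq2 called 2. No gene passed in B cells (of 2096, 56 at an unadjusted p under 0.05), NK cells (of 2620, 143) or neutrophils (of 906, 24), and DESeq2 called 0 in each. Within Kupffer cell-like clusters, where PV replicate 1 gave 4 cells, the B cell chemokine Cxcl13 was lower in PV (log2 fold change -2.60 ± 0.46 SE, edgeR adjusted p = 0.00031), at 0 and 354 UMIs in PV and 1142 and 260 in CV. These Cxcl13 UMIs lay in 0 of 4 and 42 of 120 cells in PV and in 40 of 56 and 11 of 40 in CV. The chemokine receptor Cxcr4 was higher (2.10 ± 0.48, edgeR adjusted p = 0.0367), at 11, 84, 18 and 4 UMIs, the 11 in a single cell. With shared barcodes kept Serpina3g had 30, 3, 2 and 3 UMIs in the cDC1 class and too few to be tested, and Cxcl13 and Cxcr4 had log2 fold changes of -0.77 and 1.30 and did not pass (edgeR adjusted p = 0.99995 for each). Other genes passed there: Cd8a in NK cells (1 of 2868, log2 fold change 2.56 ± 0.41, edgeR adjusted p = 0.0131), Cd207 in cDC1 (1 of 3857, -2.88 ± 0.37, 0.00075) and Cxcl9 within Kupffer cell-like clusters (1 of 5544, 2.74 ± 0.33, 0.00015), while B cells (of 2139) and neutrophils (of 906) had 0. In the same library order, Cd8a had 10, 30, 7 and 9 UMIs, Cd207 21, 5, 68 and 30, and Cxcl9 13, 220, 17 and 9. Without shared barcodes Cd8a and Cd207 did not pass (edgeR adjusted p = 0.251 and 0.999), and Cxcl9 had 0, 7, 3 and 2 UMIs and was not tested. In PV replicate 1 macrophages Spp1, which encodes osteopontin, had 997 UMIs, against 0 in the macrophages of the other libraries, and Epcam and Krt19, other genes of the cholangiocyte list, had 0.

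Immediate early and dissociation response genes did not lean the same way in every class. They were higher in PV within Kupffer cell-like clusters in 23 of 23 members (camera adjusted p = 1.3e-11, and adjusted p = 0.932 with an estimated correlation). They were lower in PV in T cells in 15 of 22 members (0.00029, and adjusted p = 0.580 with an estimated correlation) and in NK cells in 16 of 17 (3.1e-06, and adjusted p = 0.579 with an estimated correlation). Pro-inflammatory cytokines and chemokines were lower in PV in T cells, with 7 of 7 members below 0 in log2 fold change (camera adjusted p = 8.4e-08, and adjusted p = 0.580 with an estimated correlation), against a higher list in macrophages. Without Ccl3 it was 6 of 6 (camera adjusted p = 1.5e-05, and adjusted p = 0.580 with an estimated correlation). Only Ccl3, Nfkbia and Nfkbiz were lower in both PV libraries than in both CV libraries. Cxcl10, Ccl5, Ccl4 and Tnf were each higher in 1 PV library than in at least 1 CV library. The unnamed cluster led by Csf2, Ifng and Cd40lg, with 14, 46, 38 and 25 cells, lay outside these T cell sums. MHC class II genes were higher in PV in all-cell sums in 15 of 16 members (camera adjusted p = 6.7e-09, and adjusted p = 0.398 with an estimated correlation), and cytotoxicity genes lower in 16 of 17 (2.7e-12, and adjusted p = 0.262 with an estimated correlation). NK cells, which express cytotoxicity genes, made up 3.79% of PV and 12.1% of CV cells, and the dendritic cell classes cDC1 and cDC2, which express MHC class II genes, 8.06% and 4.79% of PV and 3.77% and 1.88% of CV cells. Within NK cells the cytotoxicity list had a camera adjusted p of 0.602 (median -0.14, mean 0.0698), and within T cells 0.321 (median 0.0095, with a test direction below 0). MHC class II genes were higher in PV in the T cell sums (0.0026, and adjusted p = 0.580 with an estimated correlation) and cDC1 (0.013, and adjusted p = 0.629 with an estimated correlation), and did not pass in macrophages (0.323) or B cells (0.967). RNA of other cells was not separated out of the T cell sums, so these values do not show that T cells express the genes. Past camera were 6 of 17 lists in all cells, 3 of 11 in T cells, 1 of 13 in cDC1, 2 of 7 in NK cells, 0 of 6 in B cells and 3 of 17 in Kupffer cell-like clusters, and with an estimated correlation or fry 0 in each. With shared barcodes kept it was 6 of 17, 3 of 11, 1 of 12, 1 of 9, 0 of 6 and 3 of 17, and again 0 in each with an estimated correlation or fry. Whether a list differs between classes was not tested.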
